A study of Mus musculus with 6 samples.

How the data were processed

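Total RNA was measured by sequencing in 6 libraries from V6.5, a mouse embryonic stem cell line: 3 libraries of embryonic stem cells (ESC) and 3 of epiblast-like cells (EpiLC). Per the labels' protocols, all cells were grown in a Knockout DMEM medium with 15% fetal bovine serum. The ESC medium also held leukaemia inhibitory factor (LIF) and the 2i pair of GSK3 and MEK inhibitors. The EpiLC samples were labelled as day 3 without LIF and without 2i. RNA was extracted with Trizol, depleted of ribosomal RNA with a Ribo-Zero Gold kit, and about 100 ng of depleted RNA went into a Kapa stranded library kit, per the labels' protocols.

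The authors deposited a table of raw read counts per Ensembl gene, with a column for each library. The submitters' processing notes name cutadapt, STAR, featureCounts and DESeq2 and the mouse build mm10, without versions. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical gene copies may therefore be split in ways that the counts do not show, and such genes are reported as uncertain.

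The table held 51918 rows. The 92 rows of spike-in controls held 0 counts in each library and were left out. Of the 51826 Ensembl identifiers, 51633 were matched to a symbol and position in GENCODE release M21 on GRCm38, the same assembly as mm10. The 193 without a match held at most 0.033% of any library's counts. Library totals were 20124955, 22879812 and 11499687 counts for ESC replicates 1 to 3 and 9710410, 11425054 and 11046331 counts for EpiLC replicates 1 to 3. A level of 3 counts in a library, the limit that a count of 0 allows, corresponded to 0.131 to 0.309 CPM, counts scaled to a common library total. This limit and other counting intervals cover counting error only, since the reads carried no molecular identifiers that are recorded here. The ribosomal-RNA-like locus Gm26917 took 3.48% to 4.34% of the counts, and mitochondrial genes took 0.50% to 0.61%.

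Counts were tested with edgeR 4.0.16 (quasi-likelihood fit with the legacy option off, TMM scaling) in R 4.3.3, after filterByExpr with its defaults of 10 counts per library and 15 in total. The design had the group as its single term. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are EpiLC minus ESC, so positive values are higher in EpiLC. Levels are CPM on TMM-scaled totals, as mean ± SD over the 3 libraries of a group. For a gene at 0 in each library of a group, the fold is given as a lower bound against 3 counts over that group. For a named gene with 1 to 3 counts in a group, the ratio of the counts per scaled total is given with its exact 95% interval (Clopper-Pearson, conditional on the sum of both counts).

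Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists covered naive and core pluripotency, formative epiblast, primitive streak, neural, primitive endoderm, trophectoderm, 2-cell-like, fibroblast, germline and HOX genes. Others held the grainyhead family, epithelial and mesenchymal genes, the DNA methylation machinery, imprinted genes, clustered protocadherins and the Rhox cluster. The remaining ones held the responses to LIF, ERK, WNT, NODAL, BMP and p53, glycolysis, nuclear and mitochondrial genes of respiration, ribosomal proteins, histones and cholesterol synthesis. Of the listed symbols, 2 of the 2-cell-like list (Dux and Eif1ad8) had no match, and Ccrn4l and Tex13 were matched under their current symbols Noct and Tex13b. Each list was tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 30 lists. Camera sets a list against the other genes. Fry asks whether its members move on balance in a single direction.

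The naming rule took 16 genes chosen in advance, then the 6 genes with the largest and the 6 with the most negative log2 fold change among genes that were called, did not overlap between groups and reached a mean of 10 CPM in the higher group, leaving out gene models. For each list it took up to 3 called members with the largest change and a mean of at least 1 CPM in the higher group, and let uncalled members at that level be given as values. Of the genes this rule takes, 2 are not reported here. Genes outside it are marked as named after their values were seen.

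Before use, the scripts were tested on simulated counts drawn for the genes of this comparison. After the filter 14641 simulated genes were tested, of which 194 were changed by known folds. The edgeR fit recovered 21 of the genes changed 1.5-fold that were tested (31.3%), 46 of those changed 2-fold (70.8%) and 58 of those changed 4-fold (93.5%), and called 10 of 14447 unchanged genes. Its 95% intervals covered the true value for 95.1% of genes. Far fewer genes were changed in the simulation than were called in the real data (64.6%), so these rates need not hold there. Nor does the simulation test the scaling when most genes differ. A simulated list raised 1.5-fold was called by camera in both forms and by fry, with 0 of 29 unchanged lists called by any of them. Simulated genes were drawn independently, so this check cannot show how often camera at the preset correlation calls unchanged lists whose members are correlated. In the real lists the estimated correlation ran from -0.06 (trophectoderm) to 0.80 (Rhox cluster), and was 0.46 for the ERK response.

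The alternatives were other scalings (DESeq2's size factors, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom, edgeR's test against a 2-fold threshold, a fit with the replicate number as a block, and leaving out each library in turn. Further fits were added after the data were examined. They used counts thinned to the smallest total, left out short non-coding RNAs, or removed the trend of fold change on exonic length and GC content. Exonic length was that of all annotated exons of a gene merged, which can exceed the length of the transcript present. GC content was that of the gene's longest transcript. Figures and the closing tests used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy and matplotlib 3.10.9. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.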

Results

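RNA from V6.5 mouse embryonic stem cells (ESC) kept in LIF and 2i, a medium that holds the naive pluripotent state, was compared with RNA from epiblast-like cells (EpiLC) on day 3 after both were withdrawn, with 3 libraries per state. EpiLC are cells that have left the naive state and resemble the early post-implantation epiblast. The series' title names the transcription factor GRHL2 and a transcriptional subnetwork kept after exit from naive pluripotency, and the comparison shows which transcripts differed and which did not on either side of that exit. Library totals ran from 9710410 to 22879812 counts. Levels below are mean ± SD in CPM, read counts scaled to a common library total, n = 3 libraries per state. Among the ESC libraries, replicates 1 and 2 lay closest to each other, with a chi-square per degree of freedom over genes of 2.87, while ESC replicate 3 differed from them by 29.8 and 30.4. The EpiLC pairs lay between 2.32 and 4.51. No pair agreed within sampling noise, so each library was counted once.

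The transcriptomes of the 2 states differed widely. Of 14996 genes tested with edgeR's quasi-likelihood test, 9685 (64.6%) were called at an adjusted p under 0.05, 4794 higher and 4891 lower in EpiLC. With at least a 2-fold difference, 2545 genes were higher and 1857 lower, and with at least a 4-fold difference 1244 were higher and 853 lower. In 10533 genes (70.2%) the 3 EpiLC libraries did not overlap the 3 ESC libraries, against 10% by chance. The biological coefficient of variation was 12.5%. Without ESC replicate 3, which stood apart from its group, 11731 genes were called, 9655 of them also called with all libraries, and 4872 had at least a 2-fold difference.

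**Figure D1:**
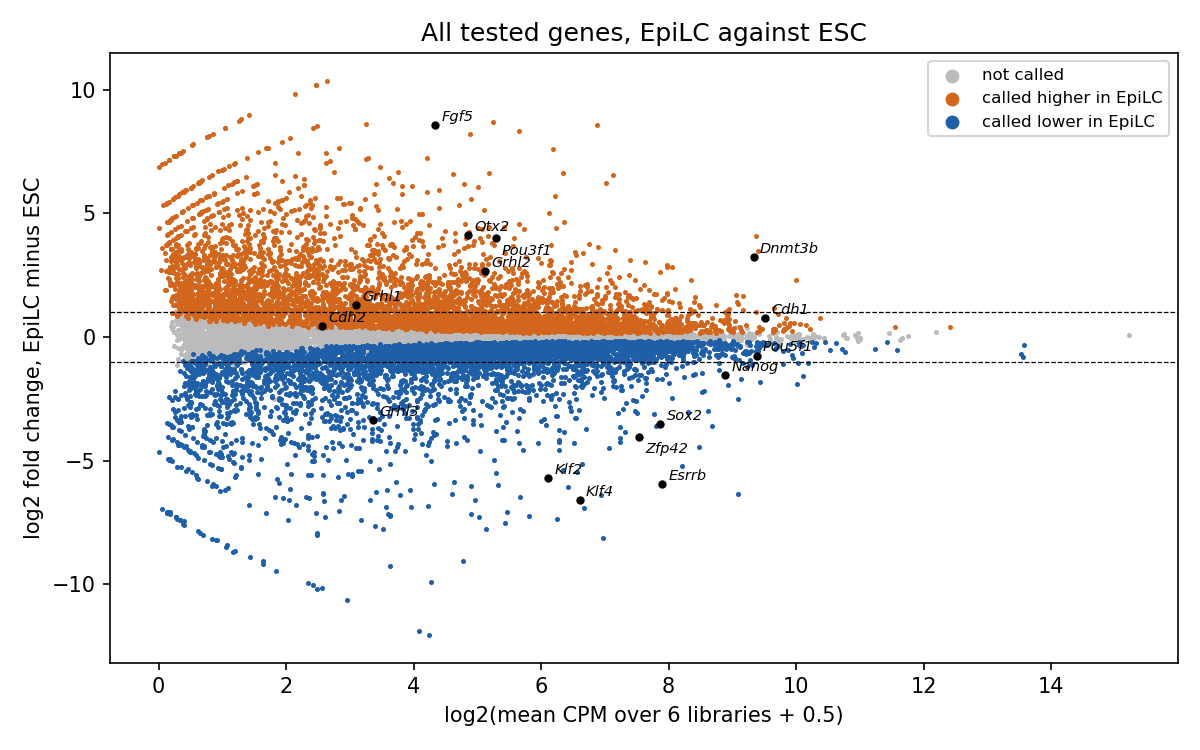
Each point is a tested gene, with log2 of its mean CPM over the 6 libraries plus 0.5 on the x axis and its log2 fold change (EpiLC minus ESC) on the y axis, coloured by whether edgeR called it, with dashed lines at 2-fold. The 16 genes chosen in advance are labelled, from Klf4 at -6.61 to Fgf5 at 8.57, and the slanted lines of points at the left are genes with few or 0 counts in a state, whose fitted values depend on the prior count.

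The factors that hold naive pluripotency fell almost throughout. Of 21 tested naive genes, 0 were higher and 19 lower in EpiLC, each of the 19 by at least 2-fold, and the median log2 fold change was -5.21. Esrrb, an orphan nuclear receptor of the naive network (ENSMUSG00000021255, chromosome 12, 86361117 to 86521628 on GRCm38, as for all positions), fell from 470 ± 89.2 to 7.62 ± 0.76 CPM, 61.8-fold. Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) fell from 191 ± 14.8 to 1.97 ± 0.52 CPM (log2 fold change -6.61, SE 0.15), and Klf2, another Krüppel-like factor, from 135 ± 22.1 to 2.54 ± 0.47 CPM. Zfp42, the marker known as Rex1, fell 16.5-fold from 350 ± 12.1 to 21.2 ± 0.86 CPM, and Nanog 2.91-fold from 704 ± 42.5 to 242 ± 1.31 CPM. The largest falls of the list were in Prdm14, a repressor of DNA methylation genes, with 1935 counts in ESC against 1 in EpiLC (ratio 1201, 95% interval 215 to 47471), in the junction protein gene Jam2 (279-fold, from 249 ± 7.90 to 0.88 ± 0.31 CPM) and in Tcl1 (184-fold). The members not called were Tcea3 (47.3 and 38.6 CPM) and Dppa3 (4.50 and 4.24 CPM), and counts of Dppa3 are uncertain because the genome holds retrocopies of it. The list was called lower by camera (adjusted p = 2.27e-47) and was the only 1 of 10 called lists to hold with an estimated correlation (adjusted p = 0.00849). Without EpiLC replicate 2, where its 1 count lay, the fitted log2 fold change of Prdm14 moved from -9.90 to -12.12.

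The core factors moved in both directions and were not called as a group. Of 12 core pluripotency genes, 3 were higher, 4 lower and 5 not called, with a median log2 fold change of -0.02 that became 0.03 with upper quartile scaling and 0.05 with library totals (camera adjusted p = 0.593). Sox2 fell 11.6-fold, from 429 ± 41.0 to 37.0 ± 2.82 CPM (log2 fold change -3.53, SE 0.10), while its partner Pou5f1, which encodes OCT4, fell 1.69-fold to 495 ± 5.30 CPM (log2 fold change -0.75, SE 0.05). Lin28a, an inhibitor of let-7 maturation, rose from 272 ± 134 to 869 ± 4.42 CPM, and the NODAL co-receptor gene Tdgf1 rose 2.26-fold from 495 ± 48.2 CPM. Sall4 (231 and 241 CPM), L1td1 (628 and 624 CPM) and Zfp281 (159 and 155 CPM) were not called. Lin28a stood at 367, 330 and 119 CPM in ESC replicates 1 to 3, so replicate 3 was the lowest. The median was 0.02 without ESC replicate 1 and 0.01 without ESC replicate 2, and the count of 4 lower became 7 without ESC replicate 3 and 2 without EpiLC replicate 1 or 2.

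**Figure D2:**
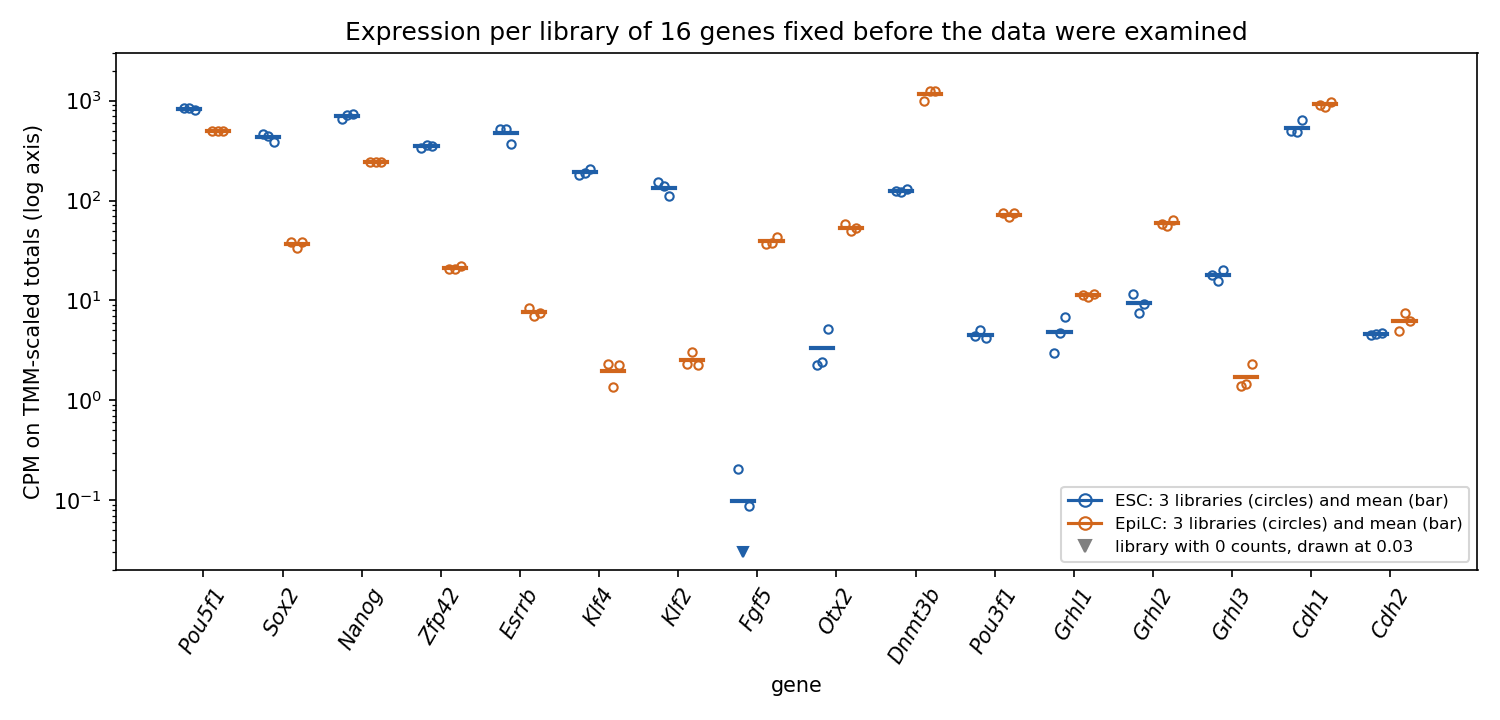
CPM on a log axis for 16 genes chosen in advance, with a circle for each library, a bar at each state's mean, and a triangle at the lower edge for a library with 0 counts. The naive genes Zfp42, Esrrb, Klf4 and Klf2 fall from means of 135 to 470 CPM to means of 1.97 to 21.2 CPM, Fgf5 rises from 0.098 to 39.2 CPM, and Grhl2 and Grhl3 move in opposite directions.

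Genes of the formative epiblast rose. Of 18 tested members, 14 were higher (12 by at least 2-fold), 1 lower and 3 not called, with a median log2 fold change of 2.13 (camera adjusted p = 8.96e-11). The list's adjusted p = 0.0787 with an estimated correlation, so that call was not kept there. Fgf5, a growth factor of the post-implantation epiblast (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030), rose from 0.098 ± 0.10 to 39.2 ± 3.45 CPM (log2 fold change 8.57, SE 0.30). That value was 9.95 without ESC replicate 1 and 7.82 without ESC replicate 2, as few reads were counted in ESC. Otx2, a homeobox factor (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819), rose from 3.31 ± 1.66 to 53.6 ± 4.28 CPM, Fgf15 from 1.23 ± 0.33 CPM by a log2 fold change of 4.07, and Pou3f1, which encodes OCT6, from 4.53 ± 0.42 to 72.5 ± 4.02 CPM. Etv5 (108 and 115 CPM), Foxd3 (16.9 and 13.8 CPM) and Tcf15 (7.05 and 5.21 CPM) were not called. The count of 1 lower, Etv4 (named after its values were seen, log2 fold change -0.60), was 2 without ESC replicate 3 and 0 without any other single library. In ESC replicate 3 the list's median lay lower than in the other ESC libraries by a log2 difference of -0.23.

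The DNA methylation machinery changed in both directions, with 5 genes higher, 5 lower and 2 not called of 12 (camera adjusted p = 0.860), a median log2 fold change of 0.21 and a mean of -0.07, the sign that camera also gave. The de novo methyltransferase Dnmt3b rose 9.29-fold, from 125 ± 4.12 to 1161 ± 149 CPM. Its catalytically inactive partner Dnmt3l fell from 363 ± 73.4 to 113 ± 8.34 CPM, and the dioxygenase Tet2, which oxidises methylcytosine, fell 12.5-fold from 277 ± 88.2 to 22.1 ± 1.49 CPM.

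The 3 grainyhead-like factors, transcription factors of epithelial genes, moved in different directions. Grhl2 (ENSMUSG00000022286, chromosome 15, 37233036 to 37363569) rose 6.30-fold, from 9.40 ± 2.11 to 59.2 ± 4.74 CPM (log2 fold change 2.66, SE 0.16, adjusted p = 3.14e-06 by edgeR). Grhl1 (ENSMUSG00000020656, chromosome 12, 24572283 to 24617391) rose 2.42-fold, from 4.85 ± 1.90 to 11.3 ± 0.39 CPM (adjusted p = 0.00220). Grhl3 (ENSMUSG00000037188, chromosome 4, 135541888 to 135573630) fell 10.2-fold, from 17.9 ± 2.18 to 1.73 ± 0.52 CPM (log2 fold change -3.35, SE 0.21, adjusted p = 3.68e-06). As a list the family was not called (camera adjusted p = 0.836).

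Epithelial genes mostly rose. Of 34 tested members, 27 were higher (22 by at least 2-fold), 4 lower (1 by at least 2-fold) and 3 not called, with a median log2 fold change of 1.90 (camera adjusted p = 1.63e-12). The adjusted p = 0.0931 with an estimated correlation. Mal2, a protein of apical transport, rose 58.2-fold from 0.55 ± 0.25 to 35.5 ± 1.16 CPM. Esrp1, a splicing regulator of epithelial cells, rose 32.6-fold from 3.97 ± 1.13 to 134 ± 4.16 CPM. Cdh1, which encodes E-cadherin (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), was already at 537 ± 84.7 CPM in ESC and rose 1.71-fold to 919 ± 55.6 CPM (log2 fold change 0.78, SE 0.11). The 4 lower genes, named after their values were seen, were the transcription factor gene Elf3 (log2 fold change -2.85), the protease inhibitor gene Spint1 (-0.77), the polarity gene Llgl2 (-0.52) and the plakoglobin gene Jup (-0.43).

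The whole 95% interval of the log2 fold change lay within 2-fold for 9 of the 34 epithelial genes (26.5%), against 8170 of all 14996 genes (54.5%), a difference that was not tested. Of those 9, 6 were nevertheless called. The other 3 were Spint2 (91.0 ± 16.7 and 98.1 ± 4.10 CPM, interval -0.19 to 0.40), Pkp3 (log2 fold change 0.01, interval -0.28 to 0.29) and Tjp3 (34.1 ± 2.53 and 31.2 ± 4.69 CPM, interval -0.41 to 0.14).

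**Figure D3:**
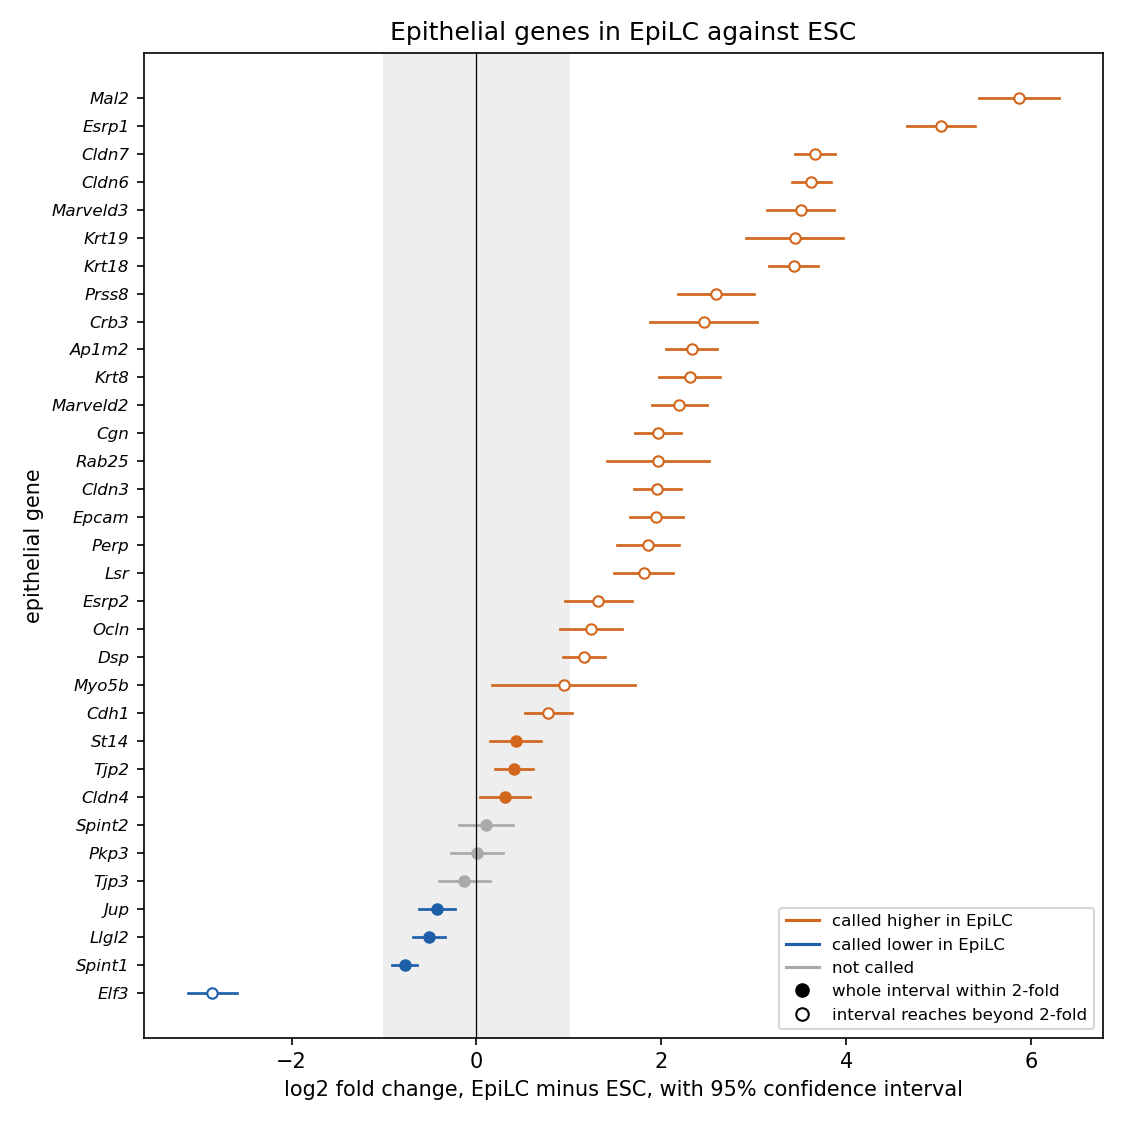
Log2 fold change (EpiLC minus ESC) of 33 of the 34 tested epithelial genes with its 95% confidence interval, the grey band marking less than 2-fold and filled points marking the 9 genes whose whole interval lies in it. Colours give the edgeR call, and the genes run from Elf3 at -2.85 to Mal2 at 5.86.

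Mesenchymal genes split evenly, with 4 higher, 4 lower and 2 not called of 10 (5 higher and 4 lower adjusted over the list alone), a median log2 fold change of 0.18 and no call by camera (adjusted p = 0.924). The forkhead gene Foxc1 rose from 0.44 ± 0.15 to 5.59 ± 1.56 CPM, whereas Zeb1, a repressor of epithelial genes, fell 10.3-fold from 30.2 ± 4.41 to 2.88 ± 1.06 CPM, and the matrix gene Tgfbi fell 7.10-fold. Cdh2, which encodes N-cadherin, stood at means of 4.60 and 6.23 CPM (log2 fold change 0.45, SE 0.18) and was not called (adjusted p = 0.0576 by edgeR, 0.0252 to 0.252 over the alternatives). It passed with upper quartile scaling (adjusted p = 0.0410), library totals (0.0358), without ESC replicate 3 (0.0291) and without EpiLC replicate 1 (0.0252).

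Of 13 LIF and STAT3 response genes, 8 were lower, 4 higher and 1 not called (median log2 fold change -1.97, camera adjusted p = 8.48e-07, adjusted p = 0.0840 with an estimated correlation). Tfcp2l1, a STAT3 target of the naive network, fell 81.4-fold from 1076 ± 204 to 13.2 ± 1.61 CPM, and Bcl3 fell 9.17-fold from 11.6 ± 0.59 CPM. This list shares Klf4, Tfcp2l1 and Gbx2 with the naive list. Camera did not call it with limma-voom (adjusted p = 0.0750) or with the length and GC trend removed (adjusted p = 0.0901). The latter was the highest over the alternatives of the list LIF and STAT3 response, the lowest being 7.85e-13. In both settings camera ran on log2 values, not on the counts. Of 16 ERK response genes, 10 were higher, 1 lower and 5 not called (median 0.60, camera adjusted p = 0.0275, adjusted p = 0.865 with an estimated correlation). Dusp6, a phosphatase induced by ERK, rose 13.4-fold from 14.4 ± 6.89 to 199 ± 17.4 CPM, and Myc rose 9.88-fold from 2.13 ± 0.90 CPM. In ESC replicate 3 the ERK list lay lower than in the other ESC libraries (median log2 difference -0.36), and its count of lower genes was 3 without that library and 0 without any other.

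NODAL targets were mostly higher, with 7 higher, 2 lower and 2 not called of 11 (7 higher and 3 lower adjusted over the list alone, median 1.14, camera adjusted p = 0.0158, adjusted p = 0.610 with an estimated correlation). Skil rose 2.74-fold to 374 ± 8.06 CPM. Lefty1, a NODAL antagonist, rose 7.07-fold from 61.1 ± 48.2 to 439 ± 14.6 CPM, with 95.4, 81.8 and 6.01 CPM in ESC replicates 1 to 3, and the list's median was lower in replicate 3 by a log2 difference of -0.29. Lefty2 (109 and 54.8 CPM) was not called. The count of 2 lower was 1 without EpiLC replicate 1 or 2. With the length and GC trend removed camera, then run on log2 values and not on the counts, did not call the list (adjusted p = 0.0563). WNT response genes went both ways, with 7 higher, 4 lower and 4 not called of 15 (camera adjusted p = 0.849, median 0.28, mean -0.14, camera direction down), and in ESC replicate 3 their median was lower than in the other ESC libraries by a log2 difference of -0.17. Cdx1 fell from 22.5 ± 9.95 to 0.32 ± 0.26 CPM (log2 fold change -6.19, or -6.97 without EpiLC replicate 1), the WNT inhibitor gene Notum fell 24.5-fold, and the ligand gene Wnt3 rose from 0.24 ± 0.18 to 13.2 ± 2.12 CPM (5.60, or 6.54 without ESC replicate 2). BMP response genes were 3 higher, 3 lower and 5 not called of 11 (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.836, median -0.10, mean 0.25, camera direction up), with Id1 up 7.55-fold to 40.9 ± 3.32 CPM, Msx1 up 5.69-fold and Id4 down 2.87-fold.

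**Figure D4:**
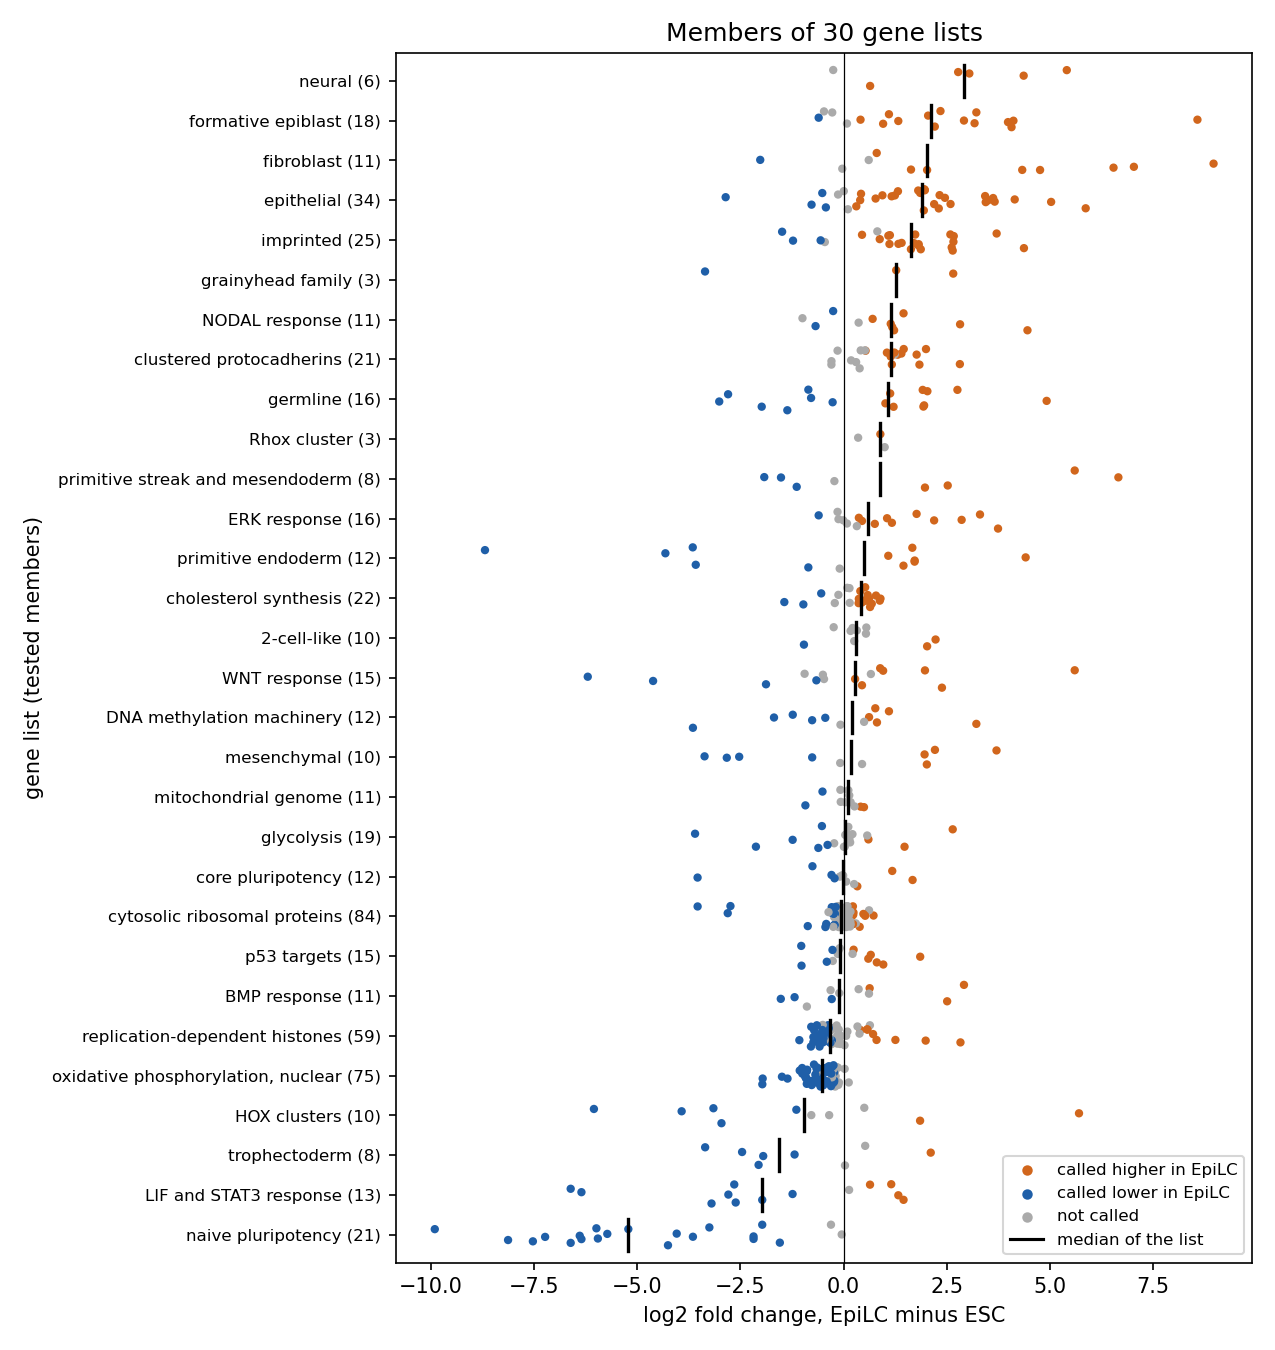
Log2 fold change (EpiLC minus ESC) of each tested member of 30 gene lists fixed in advance, coloured by the edgeR call, with a black bar at each list's median. The medians run from -5.21 (naive pluripotency, 21 genes) to 2.91 (neural, 6 genes).

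Markers of later and neighbouring lineages moved in both directions. Of 8 tested primitive streak genes, 4 were higher, 3 lower and 1 not called (camera adjusted p = 0.186). Fgf8 rose from 0.28 ± 0.22 to 25.8 ± 2.78 CPM, and Mixl1 rose 5.75-fold to 2.45 ± 0.29 CPM, while Eomes (15.1 and 13.4 CPM) was not called. Neural genes were 5 higher, 0 lower and 1 not called of 6 (median 2.91, camera adjusted p = 0.0108, adjusted p = 0.380 with an estimated correlation), and Tubb3 (51.6 and 43.4 CPM), the uncalled member, was the only 1 with a negative value. The count of 0 lower became 1 without ESC replicate 3 or without EpiLC replicate 2. The intermediate filament gene Nes rose 8.26-fold from 43.2 ± 21.2 to 352 ± 30.2 CPM. Pax6 rose from 0.20 ± 0.11 to 9.14 ± 0.37 CPM (log2 fold change 5.41, or 6.02 without ESC replicate 2), and Zic1 had 3 counts in ESC against 44 in EpiLC (ratio 23.6, 95% interval 7.57 to 119).

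Primitive endoderm genes split, with 6 higher, 5 lower and 1 not called of 12 (camera adjusted p = 0.860, median 0.49, mean -0.76, camera direction up). Dab2 rose from 0.58 ± 0.64 CPM (log2 fold change 4.41, or 5.45 without ESC replicate 3). Hnf4a fell from 3.47 ± 0.89 to 0 CPM in each EpiLC library, at least 38.0-fold lower, and Sox17 had 72 counts in ESC against 2 in EpiLC (ratio 22.3, 95% interval 5.97 to 188). The log2 fold change of Sox17 was -4.31, and -7.37 without EpiLC replicate 3. Trophectoderm genes were 1 higher, 5 lower and 2 not called of 8 (median -1.57, camera adjusted p = 0.102), with Tfap2c down 10.2-fold from 35.8 ± 1.06 CPM, Plet1 down 5.49-fold, and the keratin gene Krt7 up 4.32-fold to 5.15 ± 1.07 CPM. The count of 1 higher was 2 without ESC replicate 3. Of 10 genes of the 2-cell-like state, 2 were higher, 1 lower and 7 not called (camera adjusted p = 0.836), each at low level, and the count of 2 higher became 5 without ESC replicate 3 or without EpiLC replicate 1. The Usp17l genes (Usp17la up 4.69-fold, Usp17le up 4.07-fold) and Zscan4a (down 1.94-fold) belong to families of near-identical copies, so these values are uncertain.

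Of 11 fibroblast genes, 8 were higher, 1 lower and 2 not called (9 higher and 1 lower adjusted over the list alone, median 2.02, camera adjusted p = 2.29e-05, adjusted p = 0.412 with an estimated correlation). Tagln, an actin-binding protein of contractile cells, rose 92.9-fold from 2.95 ± 0.18 to 275 ± 23.6 CPM. Smooth muscle actin, Acta2, had 2 counts in ESC and 200 in EpiLC (ratio 161, 95% interval 44.0 to 1339), and its log2 fold change of 7.03 was 9.33 without ESC replicate 1 and 6.33 without ESC replicate 2. The proteoglycan gene Dcn rose from 0 in each ESC library to 4.33 ± 0.41 CPM, at least 76.5-fold higher. Germline genes were 9 higher and 7 lower of 16 (median 1.07, camera adjusted p = 0.695). Tdrd1 rose from 0.45 ± 0.28 to 15.0 ± 2.09 CPM (log2 fold change 4.92, or 5.62 without ESC replicate 2), while the tubulin gene Tuba3a and the meiotic gene Hormad1 fell 8.06-fold and 6.95-fold.

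Of 39 HOX genes, 10 had enough counts to be tested, with 2 higher, 5 lower and 3 not called (median -0.96, camera adjusted p = 0.381), and 4 higher without ESC replicate 3. Hoxc12 had 134 counts in ESC against 1 in EpiLC (ratio 83.2, 95% interval 14.7 to 3310), and Hoxb3 had 1 against 47 (ratio 75.7, 95% interval 12.9 to 3053). The log2 fold change of Hoxc12 moved from -6.05 to -8.27 without EpiLC replicate 3, that of Hoxb13 from -3.92 to -5.16 without EpiLC replicate 2, and that of Hoxb3 from 5.70 to 5.07 without ESC replicate 2 and 7.41 without ESC replicate 3.

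Nuclear genes of oxidative phosphorylation were lower by small amounts. Of 75, 58 were lower, 0 higher and 17 not called (61 lower and 0 higher adjusted over the list alone), 6 of them lower by at least 2-fold, with a median log2 fold change of -0.53 (camera adjusted p = 7.47e-06). The adjusted p = 0.865 with an estimated correlation. Cox7a1 fell 3.91-fold from 10.4 ± 0.51 to 2.71 ± 1.22 CPM, Ndufa4l2 fell 3.89-fold, and Ndufb4, a subunit of complex I, fell 2.81-fold from 29.2 ± 3.30 CPM. Over protein-coding genes, the median log2 fold change was -0.24 in the decile of shortest exonic length and 0.23 in the longest. The median length was 1675 bases in this list against 4500 for all protein-coding genes tested. Cytosolic ribosomal protein genes were about as short (1754.5 bases), with a median log2 fold change of -0.06. With the trend on exonic length and GC content removed, 51 were lower in the oxidative phosphorylation list and its median was -0.41. Glycolysis genes were 3 higher, 6 lower and 10 not called of 19 (camera adjusted p = 0.412, median 0.04, or -0.07 without ESC replicate 3, mean -0.14, camera direction down). Within them Pfkp, a platelet-type phosphofructokinase, fell 12.1-fold from 413 ± 38.0 to 34.1 ± 2.66 CPM and hexokinase Hk1 fell 4.35-fold. The lactate transporter gene Slc16a3 rose 6.25-fold. Ldha (996 and 1080 CPM) and Pkm (1884 and 1994 CPM) were not called. Gapdh was counted at 5.39 and 7.58 CPM, was not called, and its counts are uncertain because the genome holds many copies of it.

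Genes of the mitochondrial genome were 2 higher, 2 lower and 7 not called of 11 (camera adjusted p = 0.981, median 0.12, mean 0.01, camera direction down), with mt-Nd6 down 1.90-fold, mt-Co1 down 1.42-fold and mt-Nd4 up 1.41-fold. The count of 2 higher was 5 without ESC replicate 3 and 1 without EpiLC replicate 1, where the median was -0.01. Of 84 cytosolic ribosomal protein genes, 10 were higher, 17 lower and 57 not called (7 higher and 9 lower adjusted over the list alone, median -0.06, camera adjusted p = 0.634). With library totals the median was 0.01, with 12 genes higher and 9 lower. With the length and GC trend removed, 15 were higher and 8 lower, so the balance of calls depended on the setting. The count of lower genes was 38 without ESC replicate 3 and 9 without any other library. The count of higher genes was 6 without ESC replicate 2 or without EpiLC replicate 2. The paralogs Rpl3l, Rpl10l and Rpl39l, whose expression is known to be tissue-restricted, fell 11.6-fold, 6.99-fold and 6.67-fold. Replication-dependent histone genes were 8 higher, 28 lower and 23 not called of 59 (8 higher and 27 lower adjusted over the list alone, median -0.32, camera adjusted p = 0.286), and without ESC replicate 3 the list replication-dependent histones had 43 lower genes and was called (adjusted p = 0.00454, and 0.00454 to 0.952 over all alternatives). Hist3h2ba rose 7.12-fold to 46.2 ± 6.78 CPM. Ribosomal protein and histone genes have near-identical copies or pseudogenes, so their counts are uncertain. Cholesterol synthesis genes were 14 higher, 3 lower and 5 not called of 22 (median 0.43, camera adjusted p = 0.381), with 0 higher by at least 2-fold, Hsd17b7 up 1.86-fold, and Ebp and Tm7sf2 down 2.70-fold and 1.96-fold. Targets of p53 were 6 higher, 4 lower and 5 not called of 15 (camera adjusted p = 0.924, median -0.09, mean 0.13, camera direction up). Perp, which is also in the epithelial list, rose 3.62-fold, and the cell-cycle inhibitor gene Cdkn1a fell 2.03-fold.

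Imprinted genes were mostly higher in EpiLC. Of 25, 20 were higher (18 by at least 2-fold), 3 lower and 2 not called (20 higher and 4 lower adjusted over the list alone), with a median log2 fold change of 1.63 (camera adjusted p = 5.58e-06). The adjusted p = 0.0787 with an estimated correlation. The maternally expressed RNA H19 rose 20.7-fold from 4.68 ± 1.41 to 100.3 ± 32.4 CPM, Magel2 rose 13.1-fold to 3.28 ± 0.95 CPM, and Nnat rose 6.36-fold. Phlda2 (17.4 and 31.7 CPM) and Usp29 (3.85 and 2.83 CPM) were not called. Clustered protocadherins were 12 higher, 0 lower and 9 not called of 21 tested (median 1.14, camera adjusted p = 0.188), with Pcdhb22 up 7.05-fold to 1.26 ± 0.21 CPM. The gamma genes of this cluster share exons, so their counts are uncertain. Of 3 tested Rhox genes, 1 was higher and 2 not called (camera adjusted p = 0.849). The higher 1, Rhox6 (1.85-fold), was not called by DESeq2 (adjusted p = 0.102, and 0.00589 to 0.145 over the alternatives) or with thinned counts, and the count of higher genes was 3 without ESC replicate 3, 2 without EpiLC replicate 1 and 0 without any other library. For 22 of the 30 lists, the counts adjusted over the list alone equalled those over all genes tested, and the other 8 are given with both.

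Among named genes with the largest rise, Itgb8, an integrin subunit (ENSMUSG00000025321, chromosome 12, 119158022 to 119238802), Jakmip2 and the chloride channel gene Clic5 had 0 counts in each ESC library. Itgb8 reached 11.5 ± 1.10 CPM in EpiLC, at least 203-fold higher, and Jakmip2 (332 counts) and Clic5 (331 counts) were each at least 177-fold higher. Fndc3c1 rose from 0.21 ± 0.20 to 74.2 ± 6.50 CPM (log2 fold change 8.69, or 9.45 without ESC replicate 3). The phosphodiesterase gene Pde4b had 2 counts in ESC against 595 in EpiLC (ratio 479, 95% interval 132 to 3966). Fgf5 completed this group. Across all genes, 28 called genes had 0 counts in each ESC library and 38 had 0 in each EpiLC library.

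Among those with the largest fall, Accsl (ENSMUSG00000075023, chromosome 2, 93855361 to 93869157) and the leucine-rich repeat gene Lrrc31 (ENSMUSG00000074653, chromosome 3, 30679058 to 30699843) went from 36.8 ± 9.87 and 32.9 ± 2.65 CPM to 0 counts in each EpiLC library, at least 402-fold and 360-fold lower. Crxos and the fatty acid receptor gene Ffar3 also had 0 counts in each EpiLC library, at least 159-fold and 119-fold lower. Their ESC levels rested largely on replicate 3, at 9.08, 7.03 and 27.4 CPM for Crxos and 3.63, 4.78 and 24.2 CPM for Ffar3 in replicates 1 to 3. Without that library their fitted log2 fold changes moved from -10.62 to -9.90 and from -10.15 to -8.99. Prdm14 and Jam2 completed this group.

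Over autosomes, the median log2 fold change ran from -0.13 (chromosome 17, 722 genes) to 0.20 (chromosome 3, 752 genes), and it was 0.19 on chromosome X (511 genes). These values depended on genes with few counts. Over genes with a mean of at least 10 CPM, the chromosome 3 median log2 fold change was 0.03, the chromosome X median log2 fold change was 0.06 and the chromosome 17 median log2 fold change was -0.20. The highest autosome was then 8 (chromosome 8 median log2 fold change 0.09), and the medians of chromosomes 5, 6, 10, 14, 15 and 18 turned negative. The median over all tested genes was 0.01.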

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

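Alternatives with thinned counts, without short non-coding RNAs and with the length and GC trend removed were chosen after seeing the data; the rest were fixed before. The count of called genes, 9685, ran from 8514 (without EpiLC replicate 2) to 11731 (without ESC replicate 3) over libraries left out, and was 9161 with DESeq2, 9713 with limma-voom and 10703 of 29494 genes without a filter. The count with at least a 2-fold difference, 4402, ran from 4450 to 4872 over libraries left out and was 6043 without a filter, 4211 with thinned counts and 3102 in edgeR's test against a 2-fold threshold. With library totals in place of TMM, 54.4% of calls were higher against 49.5%. The median of all genes moved by less than 0.1 on the log2 scale under each scaling. Epithelial genes held within 2-fold numbered 9 or 10 in each setting tried. List medians changed sign for 9 lists that camera did not call. Without a filter the median was -0.40 for mesenchymal, -0.12 for germline, 0.06 for BMP response, -0.03 for glycolysis and 0.09 for HOX genes. With thinned counts it was 0.01 for core pluripotency, -0.07 for WNT response and 0.14 for BMP response, and with the length and GC trend removed -0.06 for the mitochondrial genome and 0.04 for ribosomal proteins. Upper quartile scaling and library totals turned core pluripotency (0.03 and 0.05), library totals also ribosomal proteins (0.01), and leaving out a library turned core pluripotency, glycolysis and the mitochondrial genome. The range of chromosome medians over autosomes, 0.33, was 0.29 for genes with a mean of at least 10 CPM, where most chromosome medians moved.

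The 10 lists called by camera at the preset correlation became 1 with an estimated correlation, naive pluripotency. The adjusted p of the others was then 0.0931 for epithelial genes, 0.865 for the ERK response, 0.412 for fibroblast genes, 0.0787 for formative epiblast and also for imprinted genes, 0.0840 for the LIF and STAT3 response, 0.380 for neural genes, 0.610 for the NODAL response and 0.865 for nuclear oxidative phosphorylation. That setting takes each list's correlation from these 6 libraries. With limma-voom, camera did not call the LIF and STAT3 response (adjusted p = 0.0750). With the length and GC trend removed, it called neither that list (0.0901) nor the NODAL response (0.0563). In both settings camera ran on log2 values, not on the counts, so removal of the trend was not the only change. With the trend removed, the LIF list still had 8 members lower and the NODAL list 7 higher. The cause of the lost calls was not tested. Over libraries left out, 10 or 11 lists were called, with adjusted p from 0.0116 to 0.0414 for the list ERK response and from 8.70e-04 to 0.0237 for the list NODAL response. With fry, 14 lists were called. Of the remaining comparisons of a value with an alternative, 3089 gave the same outcome, 127 moved by more than the replicate spread (1.5 times for a count), 13 newly passed the threshold and 6 no longer did. Among 104 named genes, the calls of 2, Cdh2 and Rhox6, changed under at least 1 setting. Most of the 104 were picked as called genes with the largest changes, so their steady calls follow from that choice. They do not speak for all genes: of the 9685 called, 8344 were also called without EpiLC replicate 2.

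The labels do not say whether replicate numbers pair the samples, and no pairing was visible in the counts. Deviations from the group means correlated across genes at -0.16, 0.03 and -0.24 between same-numbered ESC and EpiLC libraries. With the replicate block, 9234 genes were called, 4396 with at least a 2-fold difference, and 10 lists. Most libraries correlated best with a different number. The largest values were 0.26 between ESC replicate 2 and EpiLC replicate 3, and 0.23 between ESC replicate 3 and EpiLC replicate 1. Depth limits the low end: thinned to 9710410 counts per library, 9029 genes were called.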

Other observations

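Tests on ESC replicate 3 other than that of depth, and those on the fibroblast list, were chosen after the results were seen, as were the 5 gene lists described first. A list of contractile cytoskeleton genes and SRF and YAP targets had 18 members, of which 16 were tested as genes, and its enrichment was not tested. Of these 16, 15 were higher in EpiLC, 14 of them by at least 2-fold, and 0 lower. Thbs1, which encodes thrombospondin, went from 0.69 ± 0.47 to 234 ± 29.7 CPM, the tropomyosin gene Tpm1 from 111 ± 14.5 to 1246 ± 70.7 CPM, the calponin gene Cnn1 from 0.68 ± 0.29 to 53.8 ± 2.34 CPM, and the transcription factor gene Srf from 50.2 ± 2.06 to 119 ± 3.50 CPM. Actn1 (167 and 159 CPM) was the member not called. In a list of oocyte and early embryo genes, whose enrichment was also not tested, 6 were lower, 2 higher and 2 not called of 10 (median log2 fold change of the list -3.14). Of all 14996 tested genes, 4891 were lower. Khdc3 and Ooep, members of the subcortical maternal complex, fell from 22.6 ± 5.50 to 0.19 ± 0.11 CPM and from 149 ± 12.9 to 6.22 ± 0.18 CPM.

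In 3 families of guidance and adhesion receptors, members were called in both directions. Their enrichment was not tested, and 64.6% of all tested genes were called. Of 25 semaphorin and plexin genes, 11 were higher and 8 lower. Sema3e rose from 1.53 ± 0.58 to 160.0 ± 9.75 CPM and Sema6a from 3.35 ± 3.45 to 54.2 ± 3.27 CPM, while Sema4b fell from 70.8 ± 13.5 CPM (log2 fold change -1.77). Of 18 ephrin and EPH receptor genes, 9 were higher and 4 lower, with Efnb2 up from 5.68 ± 1.61 to 88.3 ± 6.54 CPM and Epha4 down from 78.8 ± 42.2 to 7.31 ± 1.85 CPM. Of 19 integrin genes, 6 were higher and 8 lower. The widely expressed Itgb1 rose from 292 ± 67.7 to 778 ± 27.1 CPM and Itgal fell from 8.77 ± 1.94 to 0.39 ± 0.26 CPM.

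The rise of the fibroblast list was weighed first. Fibroblasts in the EpiLC cultures would bring their collagens along with Tagln, yet Col1a1, Col1a2 and Col3a1 together reached at most 2.71% of the Tagln level in any EpiLC library (6.91 against 255 CPM on unscaled library totals, in EpiLC replicate 2). This argues against such cells as the source of Tagln. A trace of fibroblasts as the source of the low levels of Col1a1, Col1a2 and Dcn cannot be told apart from a change within the cells, since each would raise these 3 genes, and all 3 were called higher. The contractile list, with 15 members higher, was assembled after Tagln and Acta2 were seen to rise and holds both, so its count does not test an explanation or show which cells carry the RNA, and the source of Tagln stays open.

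ESC replicate 3 stood apart from ESC replicates 1 and 2. Thinned to the same total, replicates 1 and 3 had 250 of 9503 genes over 2-fold apart and replicates 1 and 2 had 0, a share of 0%, which argues against depth. Short non-coding RNAs, whose share of counts varied between libraries (snoRNAs 0.57%, 0.52% and 0.88% in ESC), made up 53 of the 225 genes over 2-fold from the mean of the others, or 23.6%, too few to be the whole cause. The naive list was not lower (median log2 difference 0.0121), against a partial move toward EpiLC. ERK targets were lower in that library (median -0.36 over 12 genes, percentile 0.14 among 10000 random lists matched on expression). Egr1, named after its values were seen, stood at 10.1, 7.21 and 0.96 CPM. A weaker ERK response in that culture may account for part of the pattern, but the NODAL (percentile 0.20), formative (1.63) and WNT (2.78) lists were low there too. These lists are not all separate, since the ERK and formative lists share Etv4 and Etv5. The random lists were not matched on correlation between members (estimated at 0.46 for the ERK list), so these percentiles can overstate how unusual each list is. They also rest on 1 library. A preparation batch shared by ESC replicate 3 and the EpiLC libraries was not tested, and the labels name no batch. Rpph1, a non-coding RNA named after its values were seen, took 1.69%, 1.65% and 1.13% of counts in ESC replicates 1 to 3. It took 0.86% to 0.92% in EpiLC. Gm42418, named likewise, went the other way (0.26%, 0.28% and 0.22%, against 0.33% to 0.36%). With such a batch, a fit without ESC replicate 3 could not separate batch from state.

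Of 525 tested loci of GENCODE's TEC and sense-intronic classes, 247 were called higher and 21 lower in EpiLC, 176 and 14 of them by at least 2-fold (median log2 fold change 0.70). Against a change of the host gene, 329 of 404 loci inside a same-strand intron had a higher log2 fold change than their host. The median difference from the host was 0.5165 (95% bootstrap interval over loci 0.45 to 0.58). Against deeper sequencing of ESC, the median of the 525 loci stayed at 0.6981 with all libraries thinned to 1 total. More intronic RNA in EpiLC libraries is a candidate explanation: the same-strand intronic loci exceeded loci outside such genes by 0.3567 (interval 0.093 to 0.590), although the latter were also higher (median 0.42), and ESC replicate 3 lay between the groups (0.27, against -0.10 and -0.15 in the other ESC and 0.48 to 0.55 in EpiLC). Both bootstrap intervals resampled loci as if independent, within the same libraries, so they do not measure the spread between libraries. Carry-over of genomic DNA was not tested, and the strand setting of the counting is not given.

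All 10 ways to split the 6 libraries into 3 and 3 were fitted. For the count of called genes, 1 split, the real one with 9685, reached that value and the highest other gave 0. For genes with at least a 2-fold difference, 1 split reached the real 4402 and the highest other gave 0. For gene lists, 6 splits, the real one with 10 included, called at least 10 and the highest other called 13. With 10 splits, no share under 0.05 can be reached. Each other split put libraries of both states into the same group, so the difference between states became spread within groups. Few or 0 called genes would follow from that alone. The counts from these splits, of genes and of lists, therefore give no level expected by chance.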
